A study of Homo sapiens with 9 samples.

How the data were processed

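Messenger RNA was measured on 9 Affymetrix oligonucleotide arrays, each with 22283 probe sets. Per the labels, 3 arrays came from septic individuals at 0 h, 3 from the same individuals at 72 h, and 3 from platelets of control individuals at 0 h. The labels number the septic individuals with the prefix ARDS, which the control titles do not carry. The individuals are called patients A, B and C and controls D, E and F here. The labels give blood cells as the source of the septic samples and name platelets only for the control samples, although the series concerns platelets. The titles of septic and control samples also begin differently, and whether both sets were prepared in the same way and place is not given in the sources used here. What 0 h is counted from is not given in the sources used here.

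The authors' deposited values are intensities on a linear scale, 1 per probe set and array. Per the labels' protocols, RNA was labelled with biotin by standard Affymetrix procedures. The software that summarised the probes is not given in the sources used here, and detection calls were not used here. The mean intensity without the lowest and highest 2% of probe sets was 150.1 on every array, so the values had been scaled to a common level before deposit. The quantiles of the arrays differed. No further normalisation was applied.

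Values were converted to log2(intensity + 16). Fold changes below are on that scale, which understates the change of dim genes. The annotation listed 20114 probe sets, of which 19071 named 1 gene and 1043 several genes. Another 2169 probe sets were unlisted and unnamed here, 2107 of them other than the 68 Affymetrix control probe sets. Of the probe sets with 1 gene, 19059 matched a RefSeq gene by Entrez identifier, and 0 symbols needed an update. No coordinates were used apart from the chromosome a gene lies on. Control probe sets and probe sets naming several genes were left out. A probe set was kept when at least 3 of the 9 arrays lay above their own median, which left 13201 probe sets. The probe set with the highest mean over all arrays stood for its gene, and 8223 genes were tested. Where another probe set of a named gene went the opposite way or moved much less, this is stated beside the gene.

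The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 6 residual and 6.4 prior degrees of freedom. All tests were two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 3 contrasts were septic 0 h against control, septic 72 h against control, and septic 72 h against septic 0 h. In total 23 gene lists with 562 entries were tested with camera, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a contrast. A list's shift is the median log2 difference of its measured members, and camera compares the list with all other genes. The number of arrays limits the precision, and limma p-values measure the spread between these samples. Those of camera at the preset correlation compare list members with other genes. They hardly account for the spread of a whole list between samples. Permutation p-values over genes do not measure that spread either. The labels number the control samples separately without stating outright that they came from separate individuals.

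Named genes followed a rule. In each contrast the rule took the 10 largest rises and 10 largest falls among called genes whose groups of arrays did not overlap. Where fewer than 3 genes passed in a direction, it took the 5 genes of smallest p in that direction, given as not past the threshold. It also took up to 4 members of smallest p of each list, and the granzymes. Not every gene the rule allowed is printed. GZMM was not in the filtered table and was not tested. The contrasts, gene lists, naming rule and alternatives were fixed before the data were examined, except those named in the closing section as chosen later.

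The patient numbers pair the septic samples, because the labels give the same individual at 0 h and 72 h. Across genes, the deviations of each patient's 2 arrays from their group means correlated at r = -0.0645 in patient A, 0.519 in patient B and -0.241 in patient C. The highest such correlation was 0.58, between patient C at 0 h and patient A at 72 h. The values of those arrays correlated at 0.892, and those of patient C's own arrays at 0.591, the lowest of any pair. Those of patient A's own arrays correlated at 0.855, the highest of any pair with patient A at 0 h. The deviations bear out the labelled pairing only for patient B, so statements about a patient's change over time rest on the labels. The fit without the block was the one planned. A replicate block was added in other fits, either as a random effect of the individual over 9 arrays or as a fixed effect over the 6 septic arrays. With 3 arrays against 3, an exact permutation test cannot give a p below 0.1.

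The calculation was tested on simulated data for septic 0 h against control, with 200 of 8223 genes changed in each of 10 runs. The fit recovered 37.2% of genes changed by a log2 value of 2, 86.2% at 3, 98.6% at 4 and 100% at 5, with 5.03% false calls. A log2 shift of 1 added to the erythroid list was called in 9 of 10 runs, with 0 other lists called. The simulated genes varied independently of each other, each with the same SD in all 3 groups, although septic arrays varied more than control arrays here. These runs therefore could not test how correlation between genes affects list calls, or how unequal spread affects recovery and false calls.

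Alternatives covered pseudocounts of 1 and 64, quantile normalisation, median centring, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, and each probe set on its own. They also covered eBayes without the trend, array weights, only the 6 arrays compared, the GAPDH 3' to 5' ratio as a covariate, the replicate block, a required fold change of 2, an estimated inter-gene correlation, and leaving out each array in turn.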

Results

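Expression profiles from 9 arrays were compared: septic individuals at 0 h and 72 h (patients A, B and C, 3 arrays per time) and control platelets at 0 h (controls D, E and F, 3 arrays). The median intensity per array lay between 35.09 and 57.57. Pairs of control arrays correlated across genes at 0.899, 0.951 and 0.907, and pairs of septic arrays at 0.591 to 0.931. Control measures of the arrays were compared between groups. The ratio of GAPDH signal at the 3' end to that at the 5' end, which rises when RNA is degraded or labelled incompletely, was 3.85 to 4.05 on the control arrays and 5.33 to 31.1 on the septic arrays. It was highest for patient A at 0 h (29.4) and patient C at 72 h (31.1). The same ratio for ACTB did not separate the groups, at 8.74 to 23.7 on control arrays and 5.14 to 32.4 on septic arrays. Bacterial poly-A control transcripts, which are added to a sample before labelling, were brighter on all 6 septic arrays than on any of the 3 control arrays. For the dap transcript the intensity was 1425 to 5693 against 2.76 to 7.04. The cre control, which is added at hybridisation, after labelling, was also brighter on every septic array, at 7802 to 39390 against 4920 to 6256. Array handling and clinical group therefore cannot be told apart in either comparison with control.

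The first comparison asks how septic samples at 0 h differed from control platelets. PLEK2, GOLGA2, MBD3 and ASCC2 rose and GP5 fell. PLEK2 (pleckstrin 2, a relative of the platelet protein pleckstrin) averaged 8.99 ± 0.418 on the log2 scale in septic samples and 5.20 ± 0.619 in controls (SD, n = 3 each), a log2 difference of 3.79 ± 0.584 (SE), or 13.8-fold. GOLGA2, which encodes a Golgi matrix protein, was higher by 3.03 (another probe set 0.666). MBD3, a subunit of a nucleosome remodelling complex, was higher by 2.84, while its other probe set differed by 0.101. ASCC2, a component of the activating signal cointegrator complex, was higher by 3.10. In controls PLEK2, GOLGA2, MBD3 and ASCC2 averaged 5.20, 4.55, 4.92 and 4.35, below the array medians of 5.88 to 6.20. At such dim values the size of the difference depends on the pseudocount. GP5, platelet glycoprotein V of the von Willebrand factor receptor, fell by 3.0, or 8.03-fold, from 8.85 ± 0.353 in controls to 5.84 ± 0.101 (SD, n = 3 each), while its other probe set differed by -0.123. The septic mean of GP5 was dim as well, below the medians of the septic 0 h arrays (5.865 to 6.018). All 5 had an adjusted p of 0.0435 in limma, and in each the 3 septic arrays lay on the same side of all 3 control arrays. The falls of smallest p below GP5 did not pass the threshold. These were TMEM70 (log2 difference -3.23, with another probe set at 0.301), TNFRSF21 (-2.29), SIAH1 (-2.36), AKAP11 (-2.63, another probe set -0.555) and MYBL1 (-3.17), with adjusted p from 0.0572 to 0.0629.

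Only these 5 of 8223 genes passed, 4 higher and 1 lower, while 1287 had an unadjusted p under 0.05, 596 higher and 691 lower. Array weights called 502 higher and 554 lower. In 26% of genes the groups did not overlap, where chance gives 10%. The count was 0 with a replicate block for the individual (smallest adjusted p = 0.0502). Without single arrays it was 1 (patient A, 0 h), 2 (B, 0 h), 0 (C, 0 h), 33 (A, 72 h), 0 (B, 72 h), 55 (C, 72 h), 0 (control D), 1 (control E) and 0 (control F), and it was 45 without both arrays of high 3' to 5' ratio.

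Erythroid transcripts rose as a group at 0 h. The median of 17 measured members was 1.94 log2 units above control (camera adjusted p = 2.28e-07), 14 of 17 were higher, and 9 passed when adjusted over the list alone while 0 passed over all genes. With an estimated inter-gene correlation the list had adjusted p = 0.651, and no list was called in this contrast. ALAS2, the erythroid enzyme that starts haem synthesis, differed by 5.21 (adjusted p = 0.0805). AHSP, the chaperone of free alpha globin, differed by 2.97, SELENBP1 by 3.66, and EPB42, a red cell membrane protein, by 3.64. Cell cycle transcripts rose too, by a median of 1.05 (adjusted p = 1.8e-07), with 22 of 23 members higher and 5 past the threshold over the list alone, but adjusted p = 0.651 with an estimated correlation. CDC20, an activator of the anaphase-promoting complex, differed by 2.58, the mitotic kinase CDK1 by 2.30 (another probe set 1.02) and the topoisomerase TOP2A by 1.67. The cell cycle list stood 1.70 and 1.96 above control on the arrays of patients A and B and at -0.0603 on that of patient C, and its median was 0.685 without patient B and 1.89 without patient C at 0 h.

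Neutrophil granule precursor transcripts rose by a median of 2.63 (adjusted p = 2.3e-05), with 15 of 15 members higher and 1 past the threshold over the list alone, but adjusted p = 0.651 with an estimated correlation. LCN2, a granule protein that binds bacterial siderophores, differed by 3.49. The list reached 6.12 above control on the array of patient B, 1.07 on that of patient C and -0.27 on that of patient A. Without patient B at 0 h its median was 0.564 and adjusted p = 0.118. Mature neutrophil transcripts rose by 0.738 (adjusted p = 0.0287, 11 of 15 higher), but adjusted p = 0.886 with an estimated correlation. The call was lost without patient B at 0 h, where the median was 0.376 (adjusted p = 0.118). It was also lost, at no smaller a median, without patient A at 0 h (0.951, adjusted p = 0.0508), without control E (0.817, adjusted p = 0.0869) or with quantile normalisation (0.842, adjusted p = 0.0686). S100A9, a calcium-binding protein abundant in neutrophils and monocytes, differed by 4.67 (adjusted p = 0.0572).

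Inflammatory cytokine and NF-kB target transcripts rose by a median of 1.04 (adjusted p = 6e-04, 17 of 20 higher, 3 past the threshold over the list alone), but had adjusted p = 0.651 with an estimated correlation. NFKBIA, the inhibitor that NF-kB induces, differed by 4.30, and the neutrophil-attracting chemokine CXCL2 by 4.18. The array of patient A, with its high 3' to 5' ratio, stood at 3 and that of patient B at -0.347. Without patient A at 0 h the list median was 0.167 and adjusted p = 0.085. Leukocyte genes raised in septic blood rose by 1.44 (adjusted p = 0.00293, 11 of 14 higher, 1 over the list alone), but had adjusted p = 0.651 with an estimated correlation. Without patient A at 0 h that median was 2.16, and without patient B 0.445 (adjusted p = 0.0486). Without patient B the inflammatory median was 1.88.

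Metabolic and structural lists moved less. Oxidative phosphorylation transcripts rose by a median of 0.335 (adjusted p = 8.15e-05, or adjusted p = 0.651 with an estimated correlation, 27 of 39 higher, 4 over the list alone), and COX6B1, a subunit of cytochrome c oxidase, differed by 2.63. Glycolysis rose by 0.588 (adjusted p = 0.00293, or adjusted p = 0.651 with an estimated correlation, 14 of 21 higher, 4 over the list alone), with HK3, a hexokinase, at 4.02 and PKM, a pyruvate kinase, at 3.29 (another probe set 0.236). Platelet cytoskeleton and integrin signalling rose by 0.486 (adjusted p = 0.00293, or adjusted p = 0.651 with an estimated correlation, 19 of 24 higher, 1 over the list alone), with the actin-binding PFN1 at 2.63 and the myosin light chain MYL9 at 4.33. Proteasome transcripts rose by 0.293 (adjusted p = 0.0104, or adjusted p = 0.792 with an estimated correlation, 19 of 29 higher, 5 over the list alone), with PSMC4 at 2.47 and PSMD8 at 2.01. Cytosolic ribosomal protein transcripts rose by 0.381 (adjusted p = 0.00853, or adjusted p = 0.886 with an estimated correlation, 29 of 41 higher). Apoptosis transcripts rose by 0.455 (adjusted p = 0.0315, or adjusted p = 0.651 with an estimated correlation, 15 of 21 higher). The platelet cytoskeleton median was 0.816 without patient B at 0 h, and its call was lost without patient C (0.118, adjusted p = 0.236). Without patient C at 0 h the medians were 0.657 for oxidative phosphorylation, 0.945 for ribosomal protein, 0.686 for proteasome and 0.761 for apoptosis. The oxidative phosphorylation median was also 0.175 without patient A and 0.508 without control F. The ribosomal call was lost with quantile normalisation (0.0252, adjusted p = 0.552) and without patient A (0.0101, adjusted p = 0.259) or patient B (0.0376, adjusted p = 0.16) at 0 h. The proteasome call was lost without patient A (0.17, adjusted p = 0.0775), patient B (-0.039, adjusted p = 0.079) or control E (0.152, adjusted p = 0.0547), and the apoptosis call without patient A (0.483, adjusted p = 0.159) or control E (0.317, adjusted p = 0.0956) or with quantile normalisation (0.444, adjusted p = 0.0646).

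T cell transcripts fell by 0.567 as a list median (adjusted p = 0.0338), with 17 of 18 members lower and 0 past the threshold over the list alone, but adjusted p = 0.886 with an estimated correlation. CD247, the zeta chain of the T cell receptor complex, differed by -1.89, and BCL11B, a T cell transcription factor, by -1.87. The list stood at -1.58 on the array of patient C, where the erythroid list (2.87) and the platelet list (1.09) had their highest values of the 9 arrays. Without that array the T cell median was -0.0405 (adjusted p = 0.68). Without patient B at 0 h it was -0.972. The call was also lost without control E (-0.501, adjusted p = 0.0869). Platelet and megakaryocyte transcripts did not pass as a list (median -5.67e-05, adjusted p = 0.937): 12 of 24 members were higher, and GP5 was the 1 called member. The arrays differed, however, with the list at -0.223, -1.72 and 1.09 for patients A, B and C and -0.179 to 0.268 on control arrays. The array of patient B also had the highest value of the granule precursor list (6.12).

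**Figure D1:**
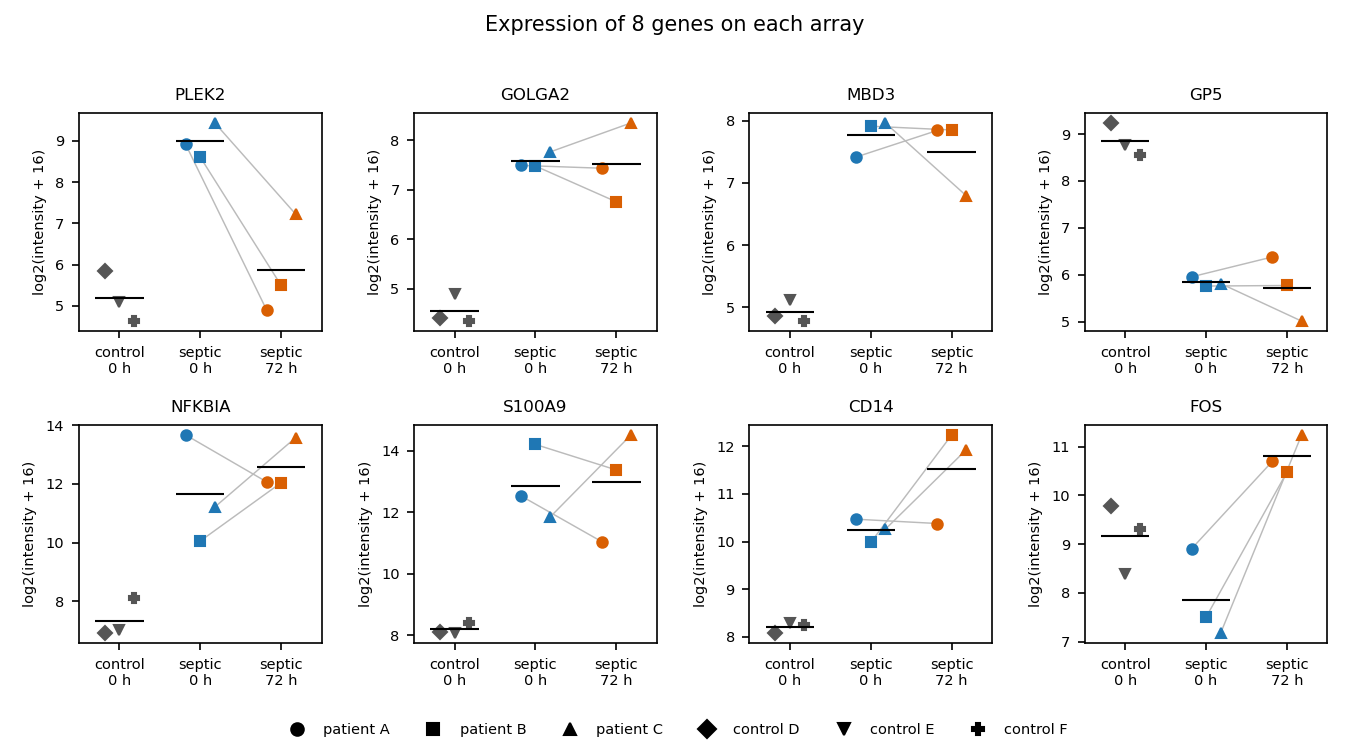
Each panel plots log2(intensity + 16) of a gene on the vertical axis for the 3 control arrays, 3 septic arrays at 0 h and 3 septic arrays at 72 h; points are arrays, horizontal lines are group means and grey lines join a patient's arrays. PLEK2 averaged 8.99 in septic samples at 0 h, 5.88 at 72 h and 5.20 in controls, while GP5 averaged 5.84, 5.72 and 8.85.

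The next comparison asks how the same individuals at 72 h differed from control platelets. NFKBIA, S100A9 and CD14 were among the genes that rose. NFKBIA was higher by 5.22 ± 0.845 (SE), or 37.3-fold, at 12.6 ± 0.877 in septic samples and 7.34 ± 0.668 in controls (SD, n = 3 each). S100A9 was higher by 4.78, and CD14, the lipopolysaccharide co-receptor of monocytes, by 3.31. The others among the 10 largest rises were NINJ1, a membrane protein of cell rupture (4.30), IFITM2, an interferon-induced antiviral membrane protein (4.23), the calcium-binding S100A11 (3.84), the major vault protein MVP (3.77), the G protein subunit GNB2 (3.39), the lysosomal protease CTSB (3.16) and SCAND1 (3.16). The 4 probe sets of CTSB ranged from -0.152 to 3.28. The falls were DLEU2, a non-coding RNA (-3.31), TMEM70, an assembly factor of mitochondrial ATP synthase (-3.21, another probe set -0.501), and GP5 (-3.13, another probe set -0.401). Each had an adjusted p of 0.0469 in limma and groups of arrays that did not overlap. In controls NINJ1, MVP, GNB2 and SCAND1 averaged 5.07, 4.71, 5.40 and 4.94, below the array medians of 5.88 to 6.20. At 72 h DLEU2 and GP5 averaged 5.88 and 5.72, near the medians of those arrays (5.675 to 5.865). The size of such differences depends on the pseudocount, and with a pseudocount of 64 only 1 gene passed, 0 higher and 1 lower.

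In all, 17 of 8223 genes passed, 14 higher and 3 lower, with 1499 at an unadjusted p under 0.05 (586 higher and 913 lower) and 27.5% with separate groups, where chance gives 10%. Array weights called 608 higher and 662 lower. Centring each array on its median called 53 higher and 3 lower. The count was 0 with a replicate block (smallest adjusted p = 0.0502). Without single arrays it was 5 (patient A, 0 h), 48 (B, 0 h), 32 (C, 0 h), 172 (A, 72 h), 0 (B, 72 h), 10 (C, 72 h), 0 (control D), 1 (control E) and 0 (control F). It was 15 without both arrays of high 3' to 5' ratio, 6 of them among the 17.

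Inflammatory cytokine and NF-kB target transcripts rose by a median of 2.08 (adjusted p = 1.82e-06), with 17 of 20 higher, 3 past the threshold over the list alone and 1 over all genes. With an estimated correlation it had adjusted p = 0.839, and no list was called in this contrast. CXCL2 differed by 4.82 (adjusted p = 0.0831) and the chemokine CCL4 by 3.46 (adjusted p = 0.122). Leukocyte genes raised in septic blood rose by 1.84 (adjusted p = 0.000138, 13 of 14 higher), and apoptosis transcripts by 0.811 (adjusted p = 0.00137, 15 of 21 higher, 1 over the list alone). Both had adjusted p = 0.839 with an estimated correlation. The leukocyte list stood at 0.0942, 1.9 and 3.15 on the 72 h arrays of patients A, B and C, and at -0.0953 to 0.135 on control arrays. The mature neutrophil list ranked these 3 patients in the same order. The apoptosis members of smallest p were BCL2A1, which opposes apoptosis, at 3.85 and CASP4, the inflammatory caspase, at 1.80, with another CASP4 probe set at -0.248. Immediate early transcripts rose by 0.944 (adjusted p = 0.0061, 13 of 19 higher, 1 over the list alone), with JUNB at 2.42 and FOS at 1.65, both subunits of the AP-1 transcription factor. The list had adjusted p = 0.867 with an estimated correlation. Without patient C at 72 h, the array of highest 3' to 5' ratio, the medians were 1.26 for inflammatory, 0.168 for apoptosis (adjusted p = 0.0469) and 0.575 for immediate early transcripts, and without patient B at 72 h that of apoptosis was 1.26.

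Mature neutrophil transcripts rose by 1.84 (adjusted p = 1.1e-05, 15 of 15 higher, 1 over the list alone), with S100A9 called and CSF3R, the receptor for granulocyte colony-stimulating factor, at 2.25 (adjusted p = 0.15). The list had adjusted p = 0.867 with an estimated correlation. It stood at 4.76 on the array of patient C, 1.37 for patient B and -0.523 for patient A. Without patient C at 72 h its median was 0.538 and adjusted p = 0.173, and without patient A it was 2.90. Neutrophil granule precursor transcripts rose by 2.35 (adjusted p = 3.09e-05, 14 of 15 higher, 1 over the list alone), with LCN2 at 3.26, but adjusted p = 0.867 with an estimated correlation. Its median was 3.65 without patient A and 1.45 without patient B at 72 h. The array of patient C at 72 h also had the highest 3' to 5' ratio.

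Platelet and megakaryocyte transcripts fell by 0.904 as a list median (adjusted p = 0.0404), with 20 of 24 members lower and GP5 past the threshold over the list alone, but adjusted p = 0.868 with an estimated correlation. CLEC1B, the platelet receptor CLEC-2, differed by -2.30 (adjusted p = 0.19). The list stood at -2.49 on the array of patient C, -1.33 for patient B and 0.771 for patient A. On the same arrays the mature neutrophil list stood at 4.76, 1.37 and -0.523, the granule precursor list at 2.88, 3.93 and -0.29, and the 3' to 5' ratio at 31.1, 5.33 and 9.84. The call was lost without patient A at 0 h (-0.904, adjusted p = 0.0509), patient B at 72 h (-0.598, adjusted p = 0.137), patient C at 72 h (-0.277, adjusted p = 0.816) or control E (-0.728, adjusted p = 0.0911). Without patient A at 72 h the median was -2.0.

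Cell cycle transcripts rose by 0.348 (adjusted p = 0.0172, 17 of 23 higher), oxidative phosphorylation by 0.16 (adjusted p = 0.0048, 22 of 39 higher, 4 over the list alone), proteasome by 0.275 (adjusted p = 0.00935, 19 of 29 higher, 6 over the list alone), glycolysis by 0.356 (adjusted p = 0.0404, 14 of 21 higher, 2 over the list alone) and platelet cytoskeleton by 0.163 (adjusted p = 0.0337, 15 of 24 higher). All 5 lists had adjusted p = 0.867 with an estimated correlation. Examples were COX6B1 at 2.47, PSMC4 at 2.28 and HK3 at 4.03. Without patient A at 72 h, cell cycle (-0.0381, adjusted p = 0.619), glycolysis (0.127, adjusted p = 0.407) and platelet cytoskeleton (0.0149, adjusted p = 0.587) lost their calls. Without patient B at 72 h, oxidative phosphorylation (-0.0481, adjusted p = 0.0555) and proteasome (0.105, adjusted p = 0.083) did. Platelet cytoskeleton also lost its call without control D (0.0593, adjusted p = 0.08) or with quantile normalisation (0.138, adjusted p = 0.148). Glycolysis did without control D (0.22, adjusted p = 0.0634) or control F (0.429, adjusted p = 0.0559), with quantile normalisation (0.416, adjusted p = 0.118) or with median centring (0.617, adjusted p = 0.052). Other medians moved without losing a call: cell cycle to 0.948, oxidative phosphorylation to 0.358 and platelet cytoskeleton to 0.319 without patient C at 72 h, and platelet cytoskeleton to 0.562 without patient B. Oxidative phosphorylation moved to 0.0267 and platelet cytoskeleton to 0.39 without control E, and oxidative phosphorylation to 0.385 without control F. Erythroid transcripts had a median of 0.581 and did not pass (adjusted p = 0.0644).

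The comparisons with control were similar to each other. The log2 differences correlated at 0.839 across genes, which are not independent replicates, against 0.501 on average in 50 simulations of unchanged groups sharing the controls. The covariance was 0.751 against 0.18, a difference of 0.571. Called genes in common were 2 higher and 1 lower. At an adjusted p under 0.1, a threshold chosen after seeing the data, 41 were higher and 11 lower in both, where independent lists would share 0.575 and 0.097 and the simulations gave 0.02 and 0. The simulated groups had no changes, so hardly any gene could pass in them and their small overlap was fixed in advance. They also drew a patient's 2 arrays independently, and each gene independently of the others. They therefore do not show how far the correlation of 0.501 could range by chance when genes vary together. The comparisons also share the septic individuals, and part of the excess over independent lists may come from the shared controls. Over all genes the median log2 difference was -0.144 at 0 h and -0.233 at 72 h.

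The change over time within the septic group was the last comparison. Erythroid transcripts fell by a median of 1.23 log2 units from 0 h to 72 h (adjusted p = 6.79e-10), with 17 of 17 members lower and 0 past the threshold over the list alone, but adjusted p = 0.748 with an estimated correlation. AHSP differed by -1.98, EPB42 by -2.32, SELENBP1 by -1.89 and CA1, the red cell carbonic anhydrase, by -2.05 (another probe set -0.247). The list fell by 0.838 in patient A, 2.57 in patient B and 1.51 in patient C. Cell cycle transcripts fell by 0.677 (adjusted p = 7.43e-07, 23 of 23 lower, 0 over the list alone), with TOP2A at -1.18 (another probe set -0.468) and CDK1 at -1.33 (another probe set -0.489), and adjusted p = 0.841 with an estimated correlation. The list fell by 0.53, 1.42 and 0.342 in patients A, B and C. Without patient B at 0 h its median was -0.43 and adjusted p = 0.0637. It was -1.35 without patient C at 0 h, -1.17 without patient A and -0.345 without patient C at 72 h. Without both arrays of high 3' to 5' ratio it was -0.102 and adjusted p = 0.225, while the erythroid median was -1.85. With the log2 ratio as a covariate the cell cycle median was -0.672 (adjusted p = 2.46e-06). That ratio changed by -1.58, -0.153 and 1.97 in patients A, B and C, which nearly cancel, so the covariate could hardly move a difference between times.

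Immediate early transcripts rose by 0.751 (adjusted p = 0.000294, 16 of 19 higher, 1 over the list alone), but had adjusted p = 0.841 with an estimated correlation. The list changed by -1, 1.60 and 1.70 in patients A, B and C, and so moved the same way as the 3' to 5' ratio in patients A and C. FOS was 7.86 ± 0.919 at 0 h and 10.8 ± 0.389 at 72 h (SD, n = 3 each), a log2 difference of 2.95 ± 0.6 (SE), and was higher in 3 of 3 patients without passing the test over all genes. JUNB differed by 1.59 and KLF6 by 1.18 (lowest probe set 0.322). Without patient B at 0 h the list median was 0.172 and adjusted p = 0.443. It was 1.27 without patient A and 0.314 without patient C at 0 h, and 0.454 without patient C at 72 h. Mature neutrophil transcripts rose by 1.12 (adjusted p = 6.54e-05, 14 of 15 higher), with AQP9 at 1.78 and CSF3R at 1.36, but adjusted p = 0.841 with an estimated correlation. The list changed by 4.61 in patient C, -0.848 in patient A and -0.23 in patient B, the same way as the 3' to 5' ratio in each. Without patient C at 72 h its median was -0.373 (adjusted p = 0.0671). It was 2.13 without patient A and 1.73 without patient B at 72 h. Inflammatory and NF-kB transcripts rose by 0.39 (adjusted p = 0.00365, 17 of 20 higher), with the chemokine CXCL1 at 2.40, but adjusted p = 0.841 with an estimated correlation. They changed by -2.41, 2.10 and 2.06 in patients A, B and C, again the same way as the 3' to 5' ratio in patients A and C. The call was lost without patient B at 0 h (-0.026, adjusted p = 0.477) or patient C at 72 h (0.365, adjusted p = 0.179), and the median was 1.17 without patient A and 0.598 without patient C at 0 h and 0.651 without patient A at 72 h. Platelet and megakaryocyte transcripts fell by 0.832 (adjusted p = 0.000497, 23 of 24 lower), with CLEC1B at -1.78, but adjusted p = 0.841 with an estimated correlation. They changed by 0.994, 0.39 and -3.58 in patients A, B and C, opposite to the mature neutrophil list and to the 3' to 5' ratio in each. The call was lost without patient C at 0 h (-0.215, adjusted p = 0.829) or at 72 h (0.014, adjusted p = 0.799), and the median was -1.58 without patient B at 0 h and -1.53 without patient A at 72 h.

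No gene passed the limma test between 72 h and 0 h (0 of 8223), with or without a replicate block for the patient, and 123 had an unadjusted p under 0.05. Groups did not overlap in 3.98% of genes. Chance gives 10% for 6 independent arrays, which these pairs from 3 patients are not, and the 3 other splits that part every pair gave 2.93%, 7.26% and 11.2%. The genes of smallest p were, among higher values at 72 h, FOS, NOD2 (1.37), ABCA7 (2.27), OGFR (1.33, lowest probe set 0.495) and KIR3DL3 (1.41), and among lower values PLEK2 (-3.11), SLAMF8 (-1.65), CLIC2 (-2.05), ANKFY1 (-1.40) and DCN (-1.50, another probe set -0.484), all with an adjusted p of 1. PLEK2, one of the genes called at 0 h, was lower at 72 h in 3 of 3 patients. With the patient as a fixed block, a list fit chosen after seeing the data, the cytotoxic granule and killer cell list was called as higher (median 0.351, adjusted p = 0.00444), which made 7 lists against 6. With an estimated correlation it had adjusted p = 0.785, and none was called.

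**Figure D2:**
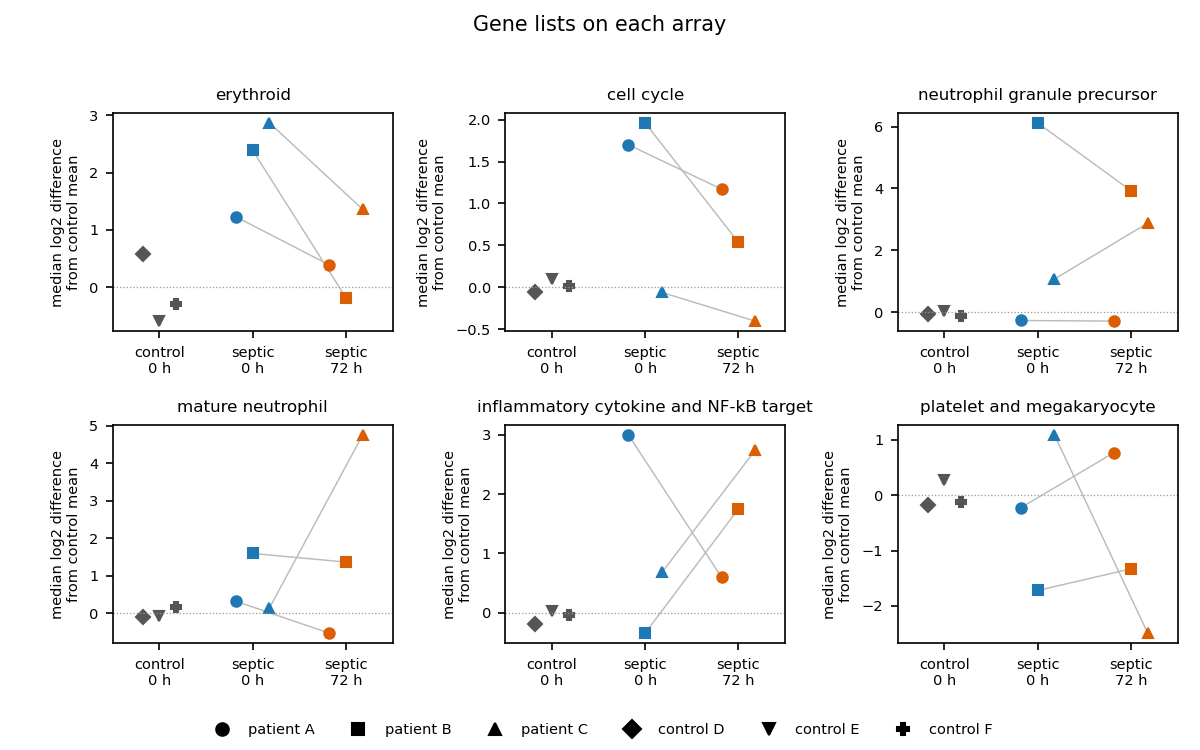
Each panel plots, for a gene list, the median over its members of the log2 difference from the control mean on the vertical axis; points are the 9 arrays, grey lines join a patient's arrays and the dotted line marks the control mean. The erythroid list was lower at 72 h in 3 of 3 patients, while the mature neutrophil list reached 4.76 only on the array of patient C at 72 h.

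Granzyme B (GZMB), a serine protease of killer cell granules and a gene of interest in a study of platelet cytotoxicity, did not differ detectably between groups. Its intensity was 364.6, 1575 and 128.1 in patients A, B and C at 0 h, 188.9, 3250 and 193.2 at 72 h, and 107.7, 474.8 and 193.9 in controls D, E and F. The log2 difference from control was 0.925 ± 1.09 (SE, n = 3 each) at 0 h (exact permutation p = 0.6, limma adjusted p = 0.701) and 1.15 ± 1.09 at 72 h (exact permutation p = 0.7, adjusted p = 0.589). Between times it was 0.227 ± 1.09 (exact permutation p = 0.8, adjusted p = 1). The smallest two-sided p that this permutation of 3 arrays against 3 allows is 0.1. Between times it did not keep the 2 arrays of a patient paired, so 0.1 is not the limit of a paired test. Patient B carried the highest values, and without patient B at 72 h the difference from control was -0.174 and that between times -1.10. With array weights the difference from control at 72 h was 2.90 (adjusted p = 0.0287). With the 3' to 5' ratio as a covariate it was 2.28 at 0 h (adjusted p = 0.446) and 2.58 at 72 h (adjusted p = 0.433). GZMA differed from control by -0.384 and -0.0826, GZMH by 0.21 and 0.85 and GZMK by -1.43 and -1.30 at 0 h and 72 h, with adjusted p from 0.506 to 0.975.

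The cytotoxic granule and killer cell list, which holds these granzymes, had a median of -0.366 at 0 h (adjusted p = 0.286) and -0.408 at 72 h (adjusted p = 0.943) against control. Its members of smallest p at 0 h were TBX21, the T-bet transcription factor (-1.42), the killer cell receptors CD160 (-1.56) and KLRF1 (-2.39), and the protease CTSW (3.23), none past the threshold over all genes. Over the list alone 1 was higher and 3 were lower. Between 72 h and 0 h the list median was 0.351 (adjusted p = 0.0724).

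**Figure D3:**
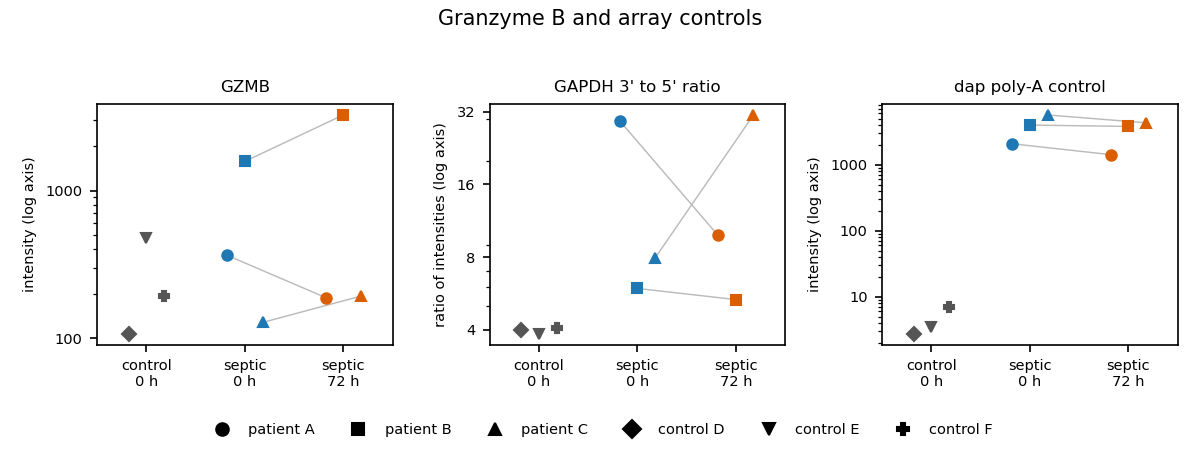
On logarithmic vertical axes, the panels plot GZMB intensity, the ratio of GAPDH 3' to 5' intensity, and the intensity of the dap poly-A control; points are the 9 arrays and grey lines join a patient's arrays. GZMB was highest for patient B (1575 and 3250), and dap was 1425 to 5693 on septic arrays and 2.76 to 7.04 on control arrays.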

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

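The septic and control arrays differed in signals outside the tested genes. The bacterial poly-A control transcripts were brighter on every septic array than on any control array. The lowest septic value over the highest control value was 202 for dap, 17 for lys, 31 for phe and 42.9 for thr. This test was chosen after the result was seen. The values fit added transcripts in the septic preparations that were absent, weaker or unlabelled in the control preparations, so a labelling step that differed between groups may account for part of the septic differences from control. The cre control, added after labelling, was brighter on every septic array too (7802 to 39390 against 4920 to 6256), so the difference in handling need not be limited to labelling. Because handling and group coincide, they cannot be told apart, and a biological difference between septic and control samples stays open as well.

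A base composition test was written before its result was seen. Genes on chromosome 19, which is rich in G and C, lay above genes on chromosomes 4 and 13, which are poor in them. The difference of medians was 0.629 at 0 h (558 and 424 genes; permutation p over genes = 0.0001, the smallest that 10000 permutations can give) and 0.583 at 72 h (permutation p = 0.0001). Between 72 h and 0 h it was -0.00111. Relative to the control mean it was 0.354 to 0.7 on the 6 septic arrays and -0.135 to 0.288 on the 3 control arrays. Of 52 genes higher at 0 h with an adjusted p under 0.1, 9 lay on chromosome 19, and of 91 at 72 h, 19 did, where 6.79% of tested genes lie there. These values are consistent with a trend in base composition or gene length between septic and control arrays, and the Spearman correlation of log2 difference with gene length was -0.256 and -0.22 across genes, against 0.0384 between times. Base composition itself was not measured here, and functional differences between chromosomes stay open.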

How the results depend on the processing

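The alternatives without both arrays of high 3' to 5' ratio, the adjusted p under 0.1 and the fixed block for lists were chosen after seeing the data. Counts of called genes depended on most settings, and the calls lay close to the threshold (adjusted p = 0.0435 and 0.0469). All 5 and 17 called genes kept their sign in every fit with a single value per gene in which they were tested, except that the stricter filter tested 4 of the 5. At 0 h against control the 5 became 20 with pseudocount 1, 2 with 64, 45 with quantile normalisation, 0 without a filter, with the stricter filter or with the mean of probe sets, 17 with every probe set, 9 without the trend, 1056 with array weights, 54 with only the 6 arrays, 35 with the 3' to 5' covariate (2 of the 5 among them), 73 at an adjusted p under 0.1 and 45 without the arrays of high ratio. At 72 h against control the 17 became 34, 1, 54, 0, 0, 0, 52, 8, 1270 and 50 under the corresponding settings from pseudocount 1 to the 6 arrays, 56 with median centring, 25 with the 3' to 5' covariate (4 of the 17 among them) and 129 at an adjusted p under 0.1. The replicate block as a random effect (consensus correlation 0.143) gave 0 in all 3 contrasts, and as a fixed effect 0 between times. Leaving out single arrays gave 0 to 55, 0 to 172, and 0 throughout between times. The cause was not tested. Between times every alternative gave 0.

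List calls numbered 13, 12 and 6, and 0 in all 3 contrasts with an estimated correlation. Leaving out single arrays gave 8 to 13, 9 to 13 and 6 to 12, and leaving out the arrays of high ratio gave 10 between times. The replicate block as a random effect kept the numbers at 13, 12 and 6. The erythroid calls at 0 h (15 of 15 alternatives) and between times (16 of 16, medians from -1.85 to -0.857) held under every alternative apart from the estimated correlation. Between times, camera's direction turned for mature neutrophil without the arrays of high ratio (-0.494) and without patient C at 72 h (-0.373; range 2.13 at most when single arrays were left out). It turned for inflammatory transcripts without patient B at 0 h (-0.026, range up to 1.17), and for platelet transcripts without patient C at 0 h, where the median stayed at -0.215 (range -1.58 to 0.014).

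GZMB differences ranged from 0.0039 to 1.74, from -0.174 to 1.82 and from -1.10 to 1.15 when single arrays were left out, array weights gave 2.90 at 72 h, and the 3' to 5' covariate gave 2.28 at 0 h and 2.58 at 72 h. GZMK against control turned to 0.066 at 0 h and 0.273 at 72 h with the 3' to 5' covariate, and to 0.19 at 72 h without the arrays of high ratio or without patient C at 72 h, and leaving out other single arrays took it as low as -2.41. The correlation of the comparisons with control ranged from 0.682 to 0.863. Among other results, 1818 values for named genes kept their side of the threshold, 158 passed it newly and 182 lost it. Only called genes could lose it, and most of the 1818 belonged to genes that were not called. Of 18 calls of printed genes, all 18 were lost without control D, control E or control F. The same held with the random block or the mean of probe sets. For arrays, signal over background limits dim genes, and no detection calls were used here.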

Other observations

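Lists not described in the report showed no shift past the threshold in any contrast. Interferon-stimulated transcripts had 15 of 27 members with separate groups at 0 h, in mixed directions: IFITM3 differed from control by 4.09 and IFIT5 by -1.61, with another IFIT5 probe set at -0.616 (list median -0.674, adjusted p = 0.772). At 72 h IFITM3 differed by 4.81 and IRF7 by 1.98, while IFI44 differed by -1.89 and HERC5 by -1.50 (median 0.0645, adjusted p = 0.594). Between times the median was 0.0292 (adjusted p = 0.161). Coagulation and fibrinolysis transcripts had medians of -0.131, -0.867 and -0.419 in the 3 contrasts (adjusted p = 0.767, 0.911 and 0.441), yet SERPINA1, an inhibitor of neutrophil elastase, differed from control at 72 h by 2.60 and PLAUR, the urokinase receptor, by 2.45 (lowest probe set 0.448), both past the threshold over the list alone.

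Monocyte transcripts had medians of -0.202, -0.0159 and -0.0523 (adjusted p = 0.327, 0.152 and 0.36), with CD14 at 2.03 and LYZ at 1.75 against control at 0 h and LILRB2 at 2.08 at 72 h. B cell transcripts had medians of -0.0446, 0.134 and 0.223 (adjusted p = 0.937, 0.594 and 0.302), with MS4A1, which encodes CD20, at -1.93 and -2.36 against control. Plasma cell medians were -0.242, 0.0153 and 0.391 (adjusted p = 0.768, 0.818 and 0.302). Those of MHC class II presentation were -0.462, -0.626 and 0.0171 (adjusted p = 0.634, 0.358 and 0.513), and those of the unfolded protein and heat shock response 0.018, 0.0218 and -0.112 (adjusted p = 0.414, 0.544 and 0.741). T cell medians were -0.638 at 72 h (adjusted p = 0.193) and 0.0763 between times (adjusted p = 0.256). Between times the remaining medians were 0.259 for granule precursor (adjusted p = 0.801), 0.247 for leukocyte genes raised in septic blood (adjusted p = 0.161), -0.297 for platelet cytoskeleton (adjusted p = 0.237), -0.267 for ribosomal protein (adjusted p = 0.0833), -0.29 for oxidative phosphorylation (adjusted p = 0.161), -0.0195 for proteasome (adjusted p = 0.732), -0.272 for glycolysis (adjusted p = 0.21) and 0.587 for apoptosis (adjusted p = 0.0565). Ribosomal protein transcripts at 72 h against control had a median of 0.0818 (adjusted p = 0.152).

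The tests of the next 2 patterns were chosen after the results were seen. Mature neutrophil transcripts were highest on the array of patient C at 72 h. The other array of high 3' to 5' ratio showed 6.83% of that shift. It came from another patient at another time, so this does not decide what RNA degradation contributed. A lower platelet share that raises every other blood cell alike would raise the T cell, B cell and monocyte lists too. The T cell list stood at -1.72 on this array, where controls spanned -0.0503 to 0.0713, but already at -1.58 in patient C at 0 h. Between these arrays the monocyte list went from -0.396 to -1.08 and the B cell list rose from -1.14 to 0.147. On this array the lists thus did not rise alike, which does not decide whether the platelet share was lower. A candidate explanation is a larger share of neutrophil RNA in this preparation, with 8 of the 15 list members above the array median on all 3 control arrays, although S100A9 does not single out this array (14.5 here, 11.04 to 14.2 on the other septic arrays, 8.07 to 8.40 in controls). A change of expression in the patient over time stays open and was not tested.

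Erythroid transcripts were lower at 72 h in 3 of 3 patients, and RNA quality is argued against: the log2 3' to 5' ratio changed by -1.58 in patient A and 1.97 in patient C, and the smaller of their list changes was -0.838. Both statements rest on the labels' pairing of the arrays, which the correlations of deviations did not bear out for patients A and C. A loss of all transcripts of non-platelet cells could not be decided by the T cell list, because its median minus the array median was -0.0838 on the array of patient C at 0 h. The largest T cell fall was 9.27% of the erythroid fall, and mature neutrophil transcripts changed by -0.848, -0.23 and 4.61 in patients A, B and C. The T cell test replaced an earlier one after that one's result was seen: the mature neutrophil change minus the erythroid change was -0.01 in the lowest of the 3 patients, which did not decide it either. In patient B the monocyte list went from -1.06 to 0.732, while granule precursor went from 6.12 to 3.93. In patient C mature neutrophil rose by 4.61, while monocyte went from -0.396 to -1.08. If the labelled pairing holds, these rises argue against a loss of all such transcripts in patients B and C. In patient A monocyte fell from 1.06 to 0.103 and the T cell list changed by 0.08, so a loss stays open there. Fewer red cell precursors or reticulocytes in the later preparations may be involved, with ALAS2 averaging 11.6 at 0 h, 9.77 at 72 h and 6.37 in controls, and 4 of 17 members above the array median on all 3 control arrays, and a change over time in the patients stays untested.

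Other groupings of the arrays were compared for each count. For septic 0 h against control, 1 of 10 splits of the 6 arrays gave as many genes as the real one, which called 5, and the highest other split called 0. For septic 72 h against control it was 1 of 10, with 17 real and 0 in the highest other. With 10 splits there are too few for a share under 0.05. Between times the real split called 0, so 10 of 10 splits called as many, and 1 other split called 728. That split set patient A at both times and patient C at 0 h against patient B at both times and patient C at 72 h, so it keeps the arrays of patients A and B together, unlike the real split, which parts all 3 pairs. The other 3 splits that part all 3 pairs called 0. The split that called 728 points to a structure of the samples other than time. The arrays on the second side were the 3 with the highest values of the granule precursor list (6.12, 3.93 and 2.88). They were also the 3 with the lowest platelet and megakaryocyte values (-1.72, -1.33 and -2.49). Leukocyte genes raised in septic blood were highest on them too (3.27, 1.9 and 3.15).

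Probe sets of the same gene differed in their changes. Within 2375 genes with several probe sets, the SD of the log2 difference was 0.702 at 0 h and 0.682 at 72 h against control, and 0.363 between times. Changes over all probe sets were larger against control too (SD 0.911 and 0.966, against 0.534), and the variance within genes was 61.5%, 51% and 46.3% of that over the same probe sets.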
